A study of Mus musculus with 2 samples.

How the data were processed

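Whole skin was profiled in 1 WT and 1 KO library by droplet single-cell RNA sequencing with a 10x Genomics 3' kit, after live cells were sorted, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode, a UMI being a tag that marks each captured molecule, so that PCR copies count once. Per the submitters' processing notes the tools and builds named are Cell Ranger 4.0.0 and GRCm38. The annotation release is not given in the sources used here. Of the 55385 features, 55144 had identifiers in GENCODE M21, from which the position of Atg16l1 was taken. The WT and KO libraries held 81919219 and 69411118 UMIs over 13579 and 9501 barcodes, with medians of 4434 and 4879 UMIs and 1865 and 1971 genes per barcode. As a check on the animals, Xist, expressed in female cells, had 113160 WT and 97460 KO UMIs, and the Y-linked genes Ddx3y and Eif2s3y had 0 in both. The Y-linked genes Kdm5d and Uty had 4 and 1 UMIs in WT and 7 and 2 in KO.

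Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which left 12001 WT and 7730 KO barcodes. The mitochondrial limit removed 1485 WT barcodes (10.9%) and 1652 KO barcodes (17.4%), and 315 and 224 barcodes had under 300 genes. Doublets were called per library with Scrublet in scanpy at its automatic threshold, which marked 652 WT (5.43%) and 187 KO (2.42%) barcodes, all removed. The 11349 WT and 7543 KO cells left were clustered together with no batch integration. Counts per 10000 were log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 nearest neighbours was divided by the Leiden method at resolution 1 into 38 clusters.

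The samples' groups, the markers of 24 cell classes, the rule for named genes and 25 gene lists were fixed before the data were examined. Clusters were named from the markers. For each class the score was the mean, over its markers, of a cluster's expression relative to the highest cluster, a marker seen in under 10% of the cluster's cells counting 0. A cluster took the best class if at least 3 of its markers were seen and the score was at least 0.25, or at least 0.15 with a marker of the class among the top 20 genes by fold. It stayed unnamed if another major class had more markers among its top 10 genes, or if its cells were shallow and lacked the class's markers there. These thresholds, and the choice to let red cell and adipocyte markers name no cluster, were set after the clusters were seen, and the clusters they left unnamed held 31.4% of WT and 12.3% of KO cells. T-like includes gamma delta T, natural killer and innate lymphoid-like clusters. Keratinocyte-like clusters were divided into basal (10 and 16), suprabasal (12), hair follicle (1, 2, 4, 5 and 17), sebaceous (23 and 35) and hair matrix or shaft (22 and 24) sub-classes. Each took the sub-class with most markers among its top 20 genes by fold, ties going to the higher score. The sub-class given thus need not be the best by score, and its score was only 0.196 in cluster 5 and 0.217 in cluster 22. With 1 library per group, a cluster mostly of 1 library may be that library and not a type.

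Counts were summed per library and class for the keratinocyte, fibroblast, macrophage or dendritic, T and endothelial-like classes and those keratinocyte sub-classes with at least 50 cells in both libraries, and given as CPM, UMIs scaled to a common class total, with exact Poisson intervals. KO over WT ratios have exact conditional (Clopper-Pearson) intervals, shares have exact Clopper-Pearson intervals and differences of shares Newcombe intervals, all at 95%. Cells are not replicates, so no p-value or standard error was computed, and all intervals cover counting error only. Genes with 0 UMIs in 1 library are given by their counts, with no fold. The depth of a class sets its precision. Among these classes the totals were highest in keratinocyte-like cells, with 40475651 WT and 40519843 KO UMIs. They were lowest at 1024214 WT UMIs in macrophage or dendritic-like cells and 466659 KO UMIs in endothelial-like cells.

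Named genes follow a fixed rule. In each class, genes needed at least 100 UMIs over both libraries and 50 CPM in 1 library, and at least 20% of the highest CPM of any class in the higher library. The classes looked at for this last limit had at least 50 cells in that library, and neutrophil-like and Langerhans-like cells were not among them. Mitochondrial, ribosomal, haemoglobin and sex-linked genes and unnamed gene models were left out. Genes were ranked by the bound of the ratio's interval nearest to 1, and the 10 highest and 10 lowest were named in all keratinocyte-like cells and 5 each way in every other class. Of each gene list, members with at least 20 UMIs were measured, up to 4 with the largest absolute log2 ratios were given as examples, and members at least 1.5 times higher or lower were counted as a size rule. The median log2 ratio used a pseudocount of 1 CPM, which understates the ratios of low genes. Its interval came from 1000 Poisson redraws, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. Some genes selected by these rules are not reported here. Of the symbols in the lists and markers 1, Krt85, was unmatched and 3 were matched by identifier. Values per cluster, and 4 further lists for pigment synthesis, dermal papilla, interleukin 17 and 22 response and mast cells, were added after the first results were seen.

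Alternatives to the filter, the doublet removal, the resolution, the joint clustering, the depth, the scaling (edgeR's TMM and DESeq2's median of ratios, used as scalings only), the summing, the sub-class mix, the minimum count and the pseudocount were computed. Log2 ratios of single genes under these alternatives also used a pseudocount of 1 CPM, so they are smaller in size than those of the plain ratios. The intervals and percentiles were tested on simulated data, independent Poisson counts drawn from the basal keratinocyte-like sums over 12648 genes. Such draws hold no clumping of UMIs in single cells and no shared changes among list members. They check the computation, and cannot show how the intervals and percentiles behave on real cells. The ratio's interval covered the true value for 93% of genes set to 2-fold, 95% of those set to 0.5-fold and 95.7% of unchanged genes. Of the simulated lists, 5.5% of unchanged lists fell outside the central 95%, while 100% of lists set to 2-fold came out above it. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.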

Results

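Single-cell RNA sequencing counts were taken from live cells, sorted by flow cytometry, of the whole skin of untreated mice. The design held 1 wild-type (WT) library and 1 knockout (KO) library, the latter from skin whose keratinocytes, the epithelial cells of the epidermis and hair follicle, lack Atg16l1. The WT library had 13579 barcodes with 81919219 unique molecular identifiers (UMIs), and the KO library had 9501 barcodes with 69411118 UMIs. After filtering, 11349 WT and 7543 KO cells were used, with 71957240 and 63074071 UMIs and medians of 4757 and 5876 UMIs per cell. With 1 library per group no difference has a replicate check, so no test was made and each value compares these 2 libraries, not the genotypes at large. Intervals are 95% and cover counting error only.

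The comparison asks how the cells of the skin and their RNA differ when keratinocytes lack Atg16l1, which encodes a protein needed to couple LC3 to the membranes of forming autophagosomes. Atg16l1 (ENSMUSG00000026289, a gene on the plus strand of chromosome 1 from 87755870 to 87792428 on GRCm38, GENCODE M21 annotation) was lower in keratinocyte-like cells of the KO library but still counted. It had 762 UMIs in WT, or 18.8 CPM (UMIs scaled to a common class total, Poisson interval 17.5 to 20.2). In KO it had 527 UMIs, or 13.01 CPM (11.9 to 14.2), a KO over WT ratio of 0.691 (0.617 to 0.773). The ratio was 0.714 (0.551 to 0.925) in basal, 0.552 (0.379 to 0.797) in suprabasal and 0.680 (0.577 to 0.7995) in hair follicle-like keratinocytes. In sebaceous-like cells it was 1.43 (0.744 to 2.96) on 12 and 46 UMIs. Outside keratinocytes it was 0.9501 (0.742 to 1.21) in fibroblast-like, 1.01 (0.563 to 1.85) in macrophage or dendritic-like, 0.740 (0.241 to 1.95) in endothelial-like and 1.55 (1.19 to 2.02) in T-like cells. Among the hair follicle-like clusters the ratio was 0.473 (0.326 to 0.670) in cluster 1, 0.621 (0.404 to 0.934) in cluster 5 and 0.533 (0.313 to 0.914) in cluster 17. It was 1.26 (0.786 to 1.95) in cluster 2 and 0.999 (0.687 to 1.47) in cluster 4. The part of the gene that was deleted is not given in the sources used here, and a 3' tag outside the deleted part checks nothing about the deletion.

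T-like cells made up a larger share of the KO library than of the WT library. They were 570 of 11349 WT cells (5.02%, exact Clopper-Pearson interval 4.63 to 5.44) and 1611 of 7543 KO cells (21.4%, 20.4 to 22.3), a difference of 16.3 percentage points (Newcombe interval 15.3 to 17.4). Most WT T-like cells were in the gamma delta T-like cluster 13, with 320 cells, and most KO T-like cells in the gamma delta T-like cluster 6, with 786, and in cluster 15, with 402. Cluster 15 is given no sub-class of T-like cells here, since Cd163l1, a gamma delta T marker, and Il7r, an innate lymphoid marker, are among its leading genes. Myeloid-like cells were 1.56% of WT and 3.31% of KO cells, and melanocyte-like cells, the pigment cells of skin and hair, were 1.97% and 3.95%. Mural-like cells, the contractile cells around vessels, were 2.19% and 1.31%, and Schwann-like cells, the glia of peripheral nerves, were 1.73% and 0.901%. Keratinocyte-like cells were 40.0% and 40.9% (0.834 points, -0.594 to 2.26) and fibroblast-like cells 14.5% and 14.7% (0.208 points, -0.815 to 1.24). Endothelial-like cells were 1.60% and 1.27% (-0.331 points, -0.669 to 0.0214). The counting intervals of these differences ran over both directions. Leaving the unnamed clusters out of the total gave -11.7, -4.36 and -0.886 points, outside those intervals, so the differences depend on how clusters were named.

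Within the keratinocyte-like cells, hair matrix or shaft-like cells were 3 of 4544 in WT (0.0660%, 0.0136 to 0.193) and 413 of 3083 in KO (13.4%, 12.2 to 14.6). Both of their clusters, 22 and 24, had the keratin genes Krt25 and Krt28 among the leading genes. Hair follicle-like cells were 78.0% (76.8 to 79.2) of WT and 51.5% (49.7 to 53.3) of KO keratinocyte-like cells. Basal-like cells were 12.5% (11.6 to 13.5) and 20.3% (18.9 to 21.8), suprabasal-like cells 7.94% (7.17 to 8.77) and 9.11% (8.12 to 10.2), and sebaceous-like cells, the lipid-filled gland cells, 1.43% (1.11 to 1.82) and 5.64% (4.86 to 6.52). Clusters without a class name were 31.4% of WT and 12.3% of KO cells: clusters 0, 7, 18 and 31 held 20.5%, 6.93%, 3.37% and 0.502% of the WT library, and clusters 11 and 27 held 8.86% and 2.07% of the KO library. With each library clustered on its own, the basal difference was 0.040 points instead of 7.79, the hair matrix difference 8.50 instead of 13.3, the hair follicle difference -13.7 instead of -26.5. The same clustering gave the mural difference as -0.382 instead of -0.882 and the fibroblast difference as 3.16 instead of 0.208. Resolution 2.0 gave 1.60 points for sebaceous-like cells instead of 4.21, and leaving the unnamed clusters out gave -11.7 and -4.36 points for keratinocyte-like and fibroblast-like cells. Sorting and the filter that left out 10.9% of WT and 17.4% of KO barcodes over 10% mitochondrial UMIs can each set such shares. With cells thinned to 1000 UMIs before clustering, to level the gap in depth, and shallower cells left out, the hair matrix or shaft-like difference was 12.7 points.

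**Figure D1:**
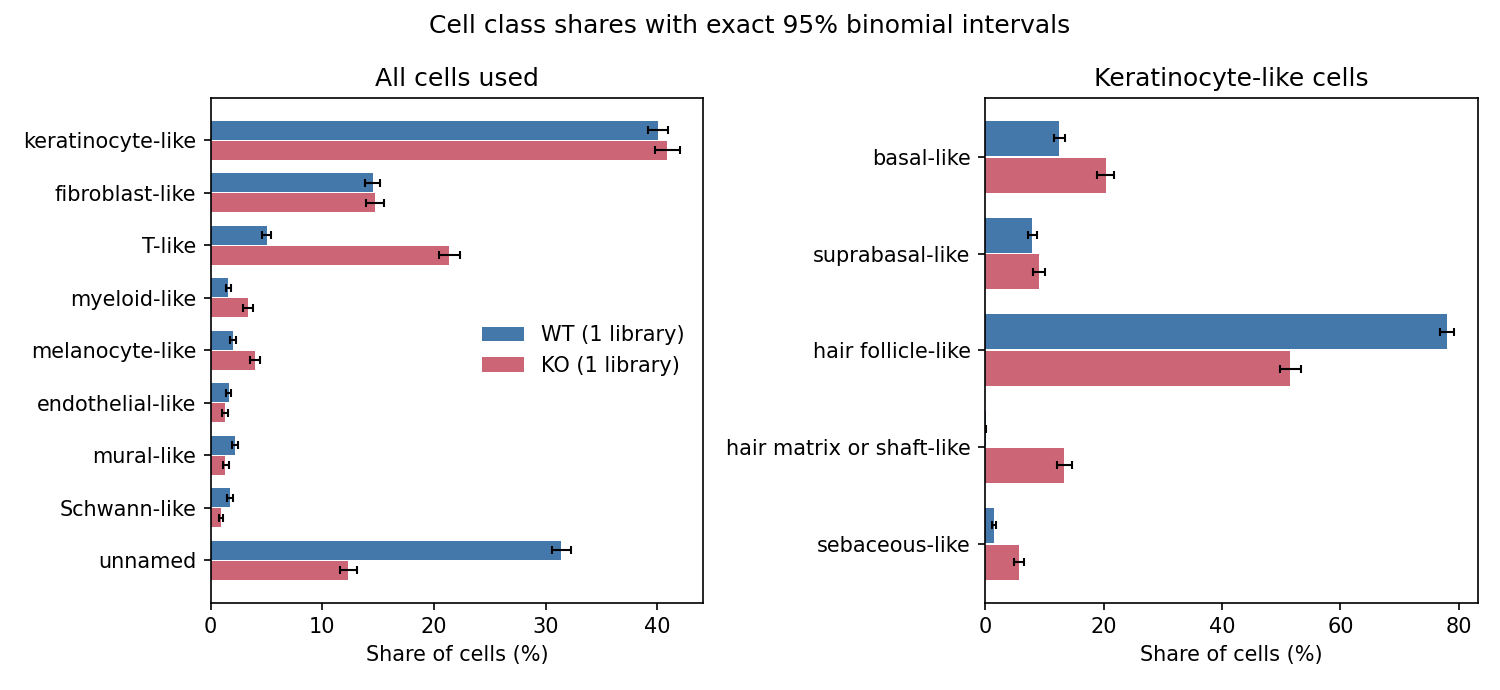
Shares of each cell class in percent of all cells used (left) and of keratinocyte-like cells (right) in the WT and KO libraries, with exact 95% binomial intervals as error bars. T-like cells reach 21.4% in KO against 5.02% in WT, and hair matrix or shaft-like cells 13.4% of keratinocyte-like cells in KO against 0.0660% in WT.

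Basal and suprabasal keratinocyte-like cells of the KO library carried more RNA of genes known from wounded or inflamed epidermis. In basal-like cells Krt6a, a keratin induced at wound edges, was 11.7 CPM in WT and 91.8 CPM in KO, a ratio of 7.82 (6.22 to 9.95). Stfa1, a stefin that inhibits cysteine proteases, was higher by 18.9 (11.1 to 34.8), and S100a8 and S100a9, the subunits of calprotectin, by 57.0 (19.3 to 278) on 3 WT UMIs and 185 (32.9 to 7345) on 1 WT UMI. Of the 9 measured members of the stress and wound list, 7 were at least 1.5 times higher and 0 at least 1.5 times lower. The median log2 ratio was 1.52 (1.38 to 1.67), at percentile 100 of 10000 matched random lists as a description of these libraries. In suprabasal-like cells 7 of 10 were higher and 0 lower, with a median of 1.39 (1.23 to 1.47), also at percentile 100. There S100a9 was higher by 31.3 (10.4 to 155) on 3 WT UMIs, Sprr2h, a cornified envelope precursor, by 12.5 (3.95 to 63.2) on 3 WT UMIs and Stfa1 by 8.03 (6.02 to 10.9). In hair follicle-like cells the median was 1.497 (1.41 to 1.53), with 9 of 11 members higher and 1 lower, S100a8 being at 27.5 (17.7 to 45.1) and S100a9 at 14.8 (9.26 to 24.8). It differed by cluster, from 2.02 in cluster 1 and 1.89 in cluster 17 to -0.058 (-0.18 to 0.78) in cluster 4 and -0.77 (-1.23 to -0.42) in cluster 2. In all keratinocyte-like cells together 10 of 14 were higher and 1 lower, with a median of 0.75 (0.65 to 0.87), S100a8 being at 22.9 (15.6 to 35.0) and S100a9 at 20.8 (13.9 to 32.5). Sebaceous-like cells had 5 of 5 members higher, with a median of 1.81 (0.98 to 2.61), such as Sprr1a at 7.67 (3.18 to 24.1) and Fosl1 at 4.36 (2.02 to 11.2). Krt6a was also high in WT cells of hair follicle-like clusters 2 and 4, at 414 and 222 CPM, against 243 and 213 CPM in KO. In clusters 1, 5 and 17 Krt6a was higher in KO.

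Among the basal-like cells' highest genes by the rule for named genes, Cstdc5, a stefin-related gene, was higher by 28.8 (20.9 to 40.8). Nppb, which encodes B-type natriuretic peptide, was higher by 23.7 (14.3 to 42.8). Stfa3 was higher by 10.2 (8.89 to 11.8) and Nrg1, a growth factor that signals through ErbB receptors, by 4.05 (3.35 to 4.93), besides Krt6a. On the lower side were Cxcl14, a chemokine of resting epidermis, at 0.249 (0.237 to 0.261), and the sulfotransferase gene Sult5a1 at 0.269 (0.233 to 0.308). Zfp36, which encodes a factor that speeds the decay of cytokine messages, was at 0.394 (0.378 to 0.410), and Ccl27a, a keratinocyte chemokine for skin-homing T cells, at 0.400 (0.388 to 0.412). Pyy, a peptide hormone gene, was at 0.00346 (0.000417 to 0.0126), with 2 KO UMIs and 41.5% of its WT UMIs in 1 cell. Both basal clusters showed the lower Cxcl14, at 0.210 in cluster 10 and 0.493 in the cycling cluster 16, but with each library clustered on its own the log2 ratio of Cxcl14 turned to 0.46. In suprabasal-like cells the epithelial transcription factor gene Ehf was higher by 11.4 (8.95 to 14.6), Cstdc5 by 9.63 (8.03 to 11.6), Zc3h12c, a ribonuclease gene, by 7.44 (5.83 to 9.62) and Stfa3 by 6.93 (5.71 to 8.48), besides Stfa1. The lower genes there were Spink5, whose product inhibits epidermal serine proteases, at 0.262 (0.229 to 0.298) and the heat shock gene Hsph1 at 0.272 (0.212 to 0.346). Spry1, an inhibitor of growth factor signalling, was at 0.291 (0.238 to 0.353), the small GTPase gene Rhob at 0.346 (0.306 to 0.390) and Cttnbp2 at 0.347 (0.294 to 0.408). Stefin genes such as Stfa1, Stfa3 and Cstdc5, and the pair Hspa1a and Hspa1b, are closely related copies. Reads may be shared among them, which was not measured, so values for single members are uncertain. Stfa3 is also among the leading genes of cluster 10. Other scalings of the class totals would move every log2 ratio by 0.15 in basal-like, 0.24 to 0.25 in suprabasal-like and -0.12 in fibroblast-like cells, by 0.093 to 0.10 in T-like and by 0.084 to 0.092 in hair follicle-like cells. The shifts were 0.066 to 0.074 in all keratinocyte-like, 0.076 to 0.079 in macrophage or dendritic-like, 0.074 in endothelial-like and -0.013 to -0.017 in sebaceous-like cells. A median closer to 0 than the shift of its class, and of the opposite sign, has no direction that holds under every scaling, which applies to the autophagy core medians of basal, suprabasal, hair follicle and fibroblast-like cells. Among others, it applies as well to the interferon-stimulated and lysosomal medians of basal and suprabasal-like cells. The p53 median of basal-like cells and the differentiation and NF-kB medians of suprabasal-like cells are further cases.

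**Figure D2:**
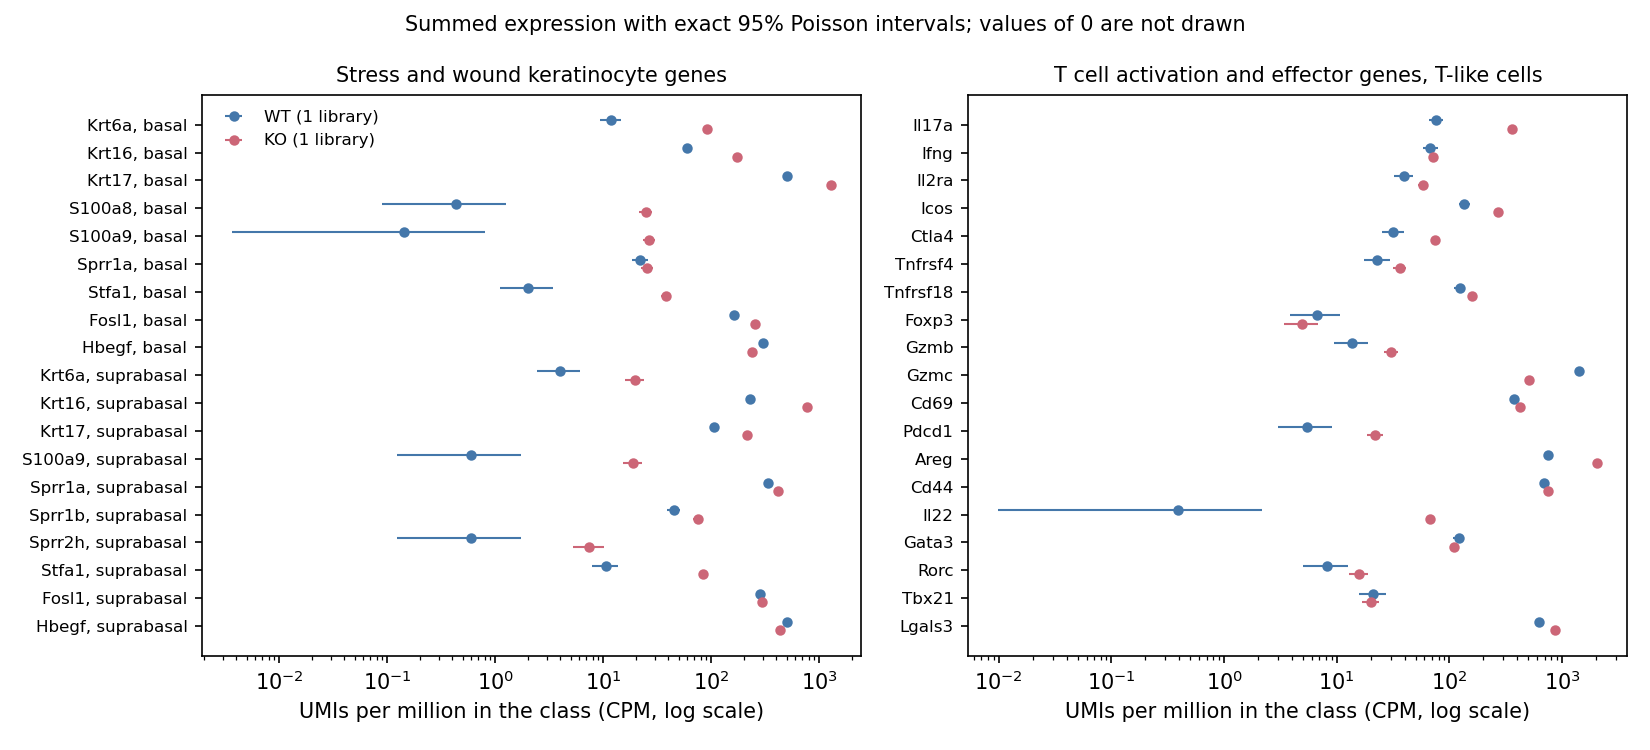
Summed expression in CPM on a log axis, with exact 95% Poisson intervals, of the stress and wound list in basal and suprabasal keratinocyte-like cells (left) and of the T cell activation list in T-like cells (right), 1 WT and 1 KO library. Krt6a in basal-like cells lies at 11.7 CPM in WT and 91.8 in KO, and Il17a in T-like cells at 76.7 and 359.

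The autophagy genes themselves differed little. Of 25 core genes in all keratinocyte-like cells, 23 lay within 1.5-fold, and the median log2 ratio was -0.087 (-0.13 to -0.038), at percentile 43.2. Vmp1, needed for autophagosome formation, was higher by 1.57 (1.46 to 1.68), Rb1cc1, a subunit of the initiating kinase complex, was at 0.692 (0.663 to 0.723), and Atg9a, which encodes the lipid scramblase of autophagosome seeds, at 0.633 (0.464 to 0.860). All 12 autophagy receptors lay within 1.5-fold (median -0.14, -0.20 to -0.11, percentile 24.5), Calcoco1 being lowest at 0.683 (0.622 to 0.749), with Wdfy3 at 0.727 (0.667 to 0.791). Of 25 lysosomal genes 5 were at least 1.5 times lower and 2 higher (median -0.21, -0.27 to -0.16, percentile 3.04). Lower were Hexa, a lysosomal glycosidase gene, at 0.457 (0.396 to 0.525) and Tfeb, a transcription factor of lysosomal genes, at 0.573 (0.489 to 0.671). Within sub-classes the lysosomal median was -0.12 in basal-like (percentile 42.9), -0.16 in suprabasal-like (71.0) and -0.12 in hair follicle-like cells (23.8). In sebaceous-like cells it was -0.15 (percentile 4.98). The autophagy core medians were -0.13 in basal-like, -0.13 in suprabasal-like, -0.070 in hair follicle-like and 0.047 in fibroblast-like cells. NRF2 targets, which answer oxidative stress, had 4 of 20 higher and 1 lower (median 0.23, 0.17 to 0.31, percentile 99.4), with Txnrd1 at 2.10 (1.94 to 2.27), Gsta4 at 2.61 (1.93 to 3.58) and Tkt at 1.90 (1.84 to 1.97). The NRF2 median was 0.069 in basal-like, 0.023 in suprabasal-like and 0.24 in hair follicle-like cells. In sebaceous-like cells it was -0.15, with 0 higher and 3 lower, and with sub-classes weighted equally it was 0.013.

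Genes of sterol synthesis and of glucose use were higher in the KO library in most keratinocyte classes. Of 17 cholesterol synthesis genes 16 were at least 1.5 times higher in all keratinocyte-like cells (median 0.84, 0.78 to 0.89, percentile 100), with Insig1 at 3.12 (2.82 to 3.45) and Sqle, which encodes squalene epoxidase, at 2.58 (2.37 to 2.80). The counts were 11 of 17 in basal-like (median 0.72), 5 of 17 in suprabasal-like (0.34) and 15 of 17 in hair follicle-like cells (1.14), with 0 lower in each. Sebaceous-like cells went the other way, with 0 higher and 9 of 17 lower (median -0.78, -0.83 to -0.59): Sc5d was at 0.197 (0.0774 to 0.467), Mvd at 0.320 (0.264 to 0.388) and Fdps at 0.373 (0.337 to 0.413). With the sub-classes weighted equally the pooled median was 0.013. In the glycolysis and hypoxia list 9 of 18 were higher and 0 lower in all keratinocyte-like cells (median 0.60, 0.57 to 0.64, percentile 100). Among them were Ddit4 at 3.02 (2.74 to 3.34), Pgk1 at 2.18 (2.09 to 2.26) and Gapdh at 2.10 (2.06 to 2.14). The same list had medians of 0.48 in basal-like, 0.58 in suprabasal-like, 0.65 in hair follicle-like, 0.49 in fibroblast-like, 0.61 in T-like, 0.78 in macrophage or dendritic-like and 0.44 in endothelial-like cells. Within clusters it ran lower in T-like cluster 6 (0.37) and fibroblast-like cluster 8 (0.36), and it was 0.11 (-0.0055 to 0.28) in hair follicle-like cluster 2. Oxidative phosphorylation genes had a median of 0.38 (0.35 to 0.42), but 17 of 18 lay within 1.5-fold, Cox5a being at 1.64 (1.60 to 1.68) and Cycs at 1.498 (1.45 to 1.55). The median was 0.18 in basal-like, 0.067 in suprabasal-like and -0.13 in sebaceous-like cells.

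Immediate early and heat shock genes, which also answer to the handling of tissue, were lower in basal, suprabasal and hair follicle-like keratinocytes of the KO library, but not in sebaceous-like cells. In basal-like cells 11 of 19 immediate early and heat shock genes were lower and 1 higher (median -0.69, -0.74 to -0.68, percentile 0). Zfp36 was at 0.394 (0.378 to 0.410), and Fos at 0.439 (0.430 to 0.448) and Jun at 0.468 (0.457 to 0.480) encode transcription factors induced within minutes of stimulation. The medians were -0.63 in suprabasal-like, -0.54 in hair follicle-like and -0.63 in all keratinocyte-like cells, where Hspa1a was higher all the same, by 2.86 (2.75 to 2.98), and Zfp36 was at 0.482 (0.473 to 0.491). Sebaceous-like cells had 4 of 19 higher and 0 lower, with a median of 0.25 (0.17 to 0.31) at percentile 99.96. Unfolded protein response genes had medians of -0.40 in basal-like cells, with 4 of 17 lower, and -0.85 in suprabasal-like cells, with 10 of 18 lower, such as the chaperone gene Hsp90b1 at 0.401 (0.365 to 0.440) and Atf3 at 0.424 (0.411 to 0.438). In all keratinocyte-like cells the median was -0.18 with 17 of 19 within 1.5-fold, Atf3 being at 0.501 (0.495 to 0.508) and Atf4 at 1.45 (1.39 to 1.498). The p53 targets had a median of -0.031 (-0.072 to 0.061), with 3 of 16 higher and 1 lower, with Pmaip1 at 1.89 (1.70 to 2.09), Eda2r at 1.95 (1.47 to 2.60) and Btg2 at 0.627 (0.616 to 0.638).

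Immune signalling genes of keratinocytes went in both directions. In the alarmin, cytokine and chemokine list 8 of 21 were higher and 3 lower (median 0.12, 0.024 to 0.23, percentile 95.5). Tnf was higher by 6.15 (4.04 to 9.70) and Cxcl1, a neutrophil chemokine, by 2.95 (2.58 to 3.38), whereas Ccl27a was at 0.279 (0.275 to 0.283) and Il34, a survival factor of Langerhans cells, at 0.346 (0.316 to 0.3797). The list's median was -0.18 in basal-like, 0.33 in suprabasal-like and 0.52 in hair follicle-like cells. NF-kB targets had a median of 0.032 (0.00075 to 0.11), with 2 of 16 higher and 1 lower, with Bcl3 at 3.69 (3.15 to 4.34) and Tnfaip2 at 1.77 (1.43 to 2.20). Interferon-stimulated genes had 8 of 22 higher and 3 lower (median 0.14, 0.031 to 0.28), with Ifi27l2a at 2.42 (2.26 to 2.58) and Gbp2 at 0.410 (0.341 to 0.492), but the median was -0.077 in basal-like and 0.45 in hair follicle-like cells. MHC class II genes had 3 of 6 lower and 0 higher (median -0.56), H2-Aa being at 0.478 (0.408 to 0.559) and H2-Ab1 at 0.589 (0.513 to 0.676). Their median was -0.55 in suprabasal-like and -0.24 in hair follicle-like cells but 0.13 (-0.12 to 0.27) in basal-like cells. Of 11 MHC class I genes 10 lay within 1.5-fold (median -0.096, but 0.26 in hair follicle-like cells), with H2-T23 at 0.603 (0.583 to 0.624) and Tapbp at 0.749 (0.711 to 0.789). Genes of T cells and macrophages were counted in keratinocyte-like cells too. Of 13 T cell activation genes 6 were higher and 2 lower (median 0.46), with Il17a at 14.7 (8.89 to 26.2) and Icos at 15.3 (6.77 to 42.8), but the median was -0.30 in hair follicle-like cells and -0.20 with cells thinned to 1000 UMIs. Of 11 macrophage polarisation genes 7 were lower and 2 higher (median -0.36), the latter being Gpnmb at 7.79 (6.54 to 9.33) and Tnf. Il17a stood at 7.93 CPM in KO basal-like cells and 359 CPM in KO T-like cells.

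Pooled over all keratinocyte-like cells, cycling and hair genes stood out. Of 22 cell cycle genes 21 were higher (median 1.38, 1.33 to 1.41), with the nucleotide synthesis genes Tk1 at 3.65 (3.33 to 4.01) and Rrm2 at 3.59 (3.30 to 3.90). In basal-like cells 0 of 22 passed 1.5-fold (median 0.10), and the basal clusters went opposite ways, at 0.44 (0.34 to 0.62) in cluster 10 and -0.25 (-0.28 to -0.20) in the cycling cluster 16. Hair follicle-like cells had 15 of 22 higher and 1 lower (median 0.99), with 0.69 in cluster 1, 0.89 in cluster 4, 0.41 in cluster 17 and -0.097 (-0.41 to 0.055) in cluster 2. The pooled median was 0.79 without hair matrix or shaft-like cells and 0.20 with sub-classes weighted equally. The rule for named genes, which ranks by the interval bound nearest to 1, gave 10 highest genes. Among them were Cstdc5 (13.2), S100a3 (12.6), the epidermal protease gene Klk7 (6.13), Stfa3 (5.51) and AI506816 (4.71). The others were the DNA replication gene Pclaf (4.62), Tk1, Spc24 of the kinetochore (3.64), Krt16 (3.56) and the fatty acid binding protein gene Fabp5 (3.46). S100a3 had 36.2% of its KO UMIs in 1 cell, and S100a3, Klk7, Stfa3, Pclaf, Fabp5, Krt16 and Tk1 are among the leading genes of 1 or 2 clusters each. Klk7 and Tk1 turned to log2 ratios of -0.67 and -1.22 in suprabasal-like cells alone, and Fabp5 to -0.075 with sub-classes weighted equally. The 10 lowest were Myoc (0.0787), Wfdc3 (0.153), Pdzrn4 (0.168), the potassium channel gene Kcnk2 (0.229), the interleukin 31 receptor gene Il31ra (0.254), Plxna2 (0.271), the tendon transcription factor gene Scx (0.271), Abi3bp (0.275), Ccl27a (0.279) and Sult5a1 (0.293). All but Myoc are leading genes of hair follicle-like clusters 1, 2, 4 or 5, and clusters 1 and 2 held 1215 and 1098 WT but 353 and 132 KO cells. In basal-like cells alone Pdzrn4 and Kcnk2 turned to 0.14 and 0.82, and Kcnk2 to 1.10 in suprabasal-like cells.

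Hair follicle stem cell genes had 9 of 16 lower and 1 higher (median -0.66, -0.75 to -0.63, percentile 0). Fgf18, a growth factor of resting follicles, was at 0.111 (0.0863 to 0.1402) and Cd34, a marker of the follicle bulge, at 0.220 (0.209 to 0.232). Within hair follicle-like cells 7 of 16 were lower and 2 higher (median -0.38), and in basal-like cells the median was 0.13. Lgr5, Lhx2, Postn and Krt15 of this list are among the leading genes of cluster 2, with 1098 WT and 132 KO cells. Sox9, Lhx2, Krt15 and Tbx1 are among those of cluster 4, with 402 WT and 534 KO cells. No median by cluster was computed, so the hair follicle-like value does not separate expression from the mix of clusters. Basal keratinocyte genes had 6 of 15 lower and 0 higher (median -0.46, -0.50 to -0.42), with Krt15 at 0.448 (0.446 to 0.451) and Lamb3 at 0.489 (0.471 to 0.508). In basal-like cells 14 of 15 lay within 1.5-fold. Differentiation genes had 7 of 19 higher and 1 lower (median 0.26, 0.15 to 0.28). Klk7 was at 6.13 (5.46 to 6.89) and Cnfn at 14.6 (6.81 to 37.1). Flg, the filaggrin gene, had 0 WT and 139 KO UMIs. Their median was 0.90 in hair follicle-like and -0.076 in suprabasal-like cells. The hair follicle-like value of these differentiation genes was not computed by cluster either, so it holds the mix of clusters too. Sebaceous and lipid synthesis genes had 10 of 18 higher and 0 lower (median 0.60, 0.50 to 0.65), with Scd2, a desaturase gene, at 3.23 (3.02 to 3.46) and Soat1 at 2.31 (2.14 to 2.48), but the median was -0.39 in suprabasal-like cells and -0.28 with sub-classes weighted equally. In sebaceous-like cells themselves 2 of 18 were higher and 7 lower (median -0.27, -0.48 to -0.20). Within hair follicle-like cells genes among the highest by rule were the chitinase-like gene Chil1 (25.6), the kallikrein genes Klk8 (23.5) and Klk7 (14.5) and Gpx2 of peroxide detoxification (10.7). The lowest were Myoc (0.106), Wfdc3 (0.2497), Plxna2 (0.259), Pdzrn4 (0.268) and S100a4 (0.312). Chil1 and Klk7 are among the genes that lead cluster 17, which held 170 WT and 297 KO cells, and Wfdc3, Plxna2 and Pdzrn4 lead cluster 2.

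By the median of their list, extracellular matrix genes were lower in each compared class of keratinocyte-like cells of the KO library, and haemoglobin RNA went both ways by class. Extracellular matrix genes, which keratinocytes and leukocytes express little, had 14 of 21 lower and 1 higher in keratinocyte-like cells (median -0.82, -0.96 to -0.67), with Col1a1, the type I collagen gene, at 0.133 (0.122 to 0.145) and Col3a1 at 0.182 (0.167 to 0.199). Their medians were -0.46 in basal-like, -0.96 in suprabasal-like, -0.83 in hair follicle-like, -1.01 in T-like, -2.36 in macrophage or dendritic-like and -2.72 in sebaceous-like cells. Endothelial-like cells differed, with a median of 0.15 (-0.045 to 0.45), 5 of 17 matrix genes being higher and 0 lower. In basal-like cells 9 of 18 were lower and 4 higher, and in suprabasal-like cells 10 of 16 were lower and 3 higher. Col1a1 was 108 CPM in WT and 15.8 in KO basal-like cells, against 30265 and 6468 CPM in fibroblast-like cells. The free RNA list had a median of -0.081 (-0.098 to -0.060) in keratinocyte-like cells, 4 of 11 being lower and 0 higher, but 0.29 in hair follicle-like cells. Lower in the pooled cells were the nuclear RNA Malat1 at 0.549 (0.548 to 0.551) and Hba-a2 at 0.554 (0.522 to 0.589). Its haemoglobin genes went both ways. Hba-a2 was at 0.110 (0.0831 to 0.143) in basal-like and 0.0246 (0.0161 to 0.0359) in suprabasal-like cells, while Hba-a1 was at 14.1 (10.98 to 18.5) in T-like and Hba-a2 at 90.5 (51.3 to 176) in endothelial-like cells. Cxcl14 and Ccl27a were also lower in T-like cells, at 0.334 (0.275 to 0.405) and 0.328 (0.269 to 0.399).

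**Figure D3:**
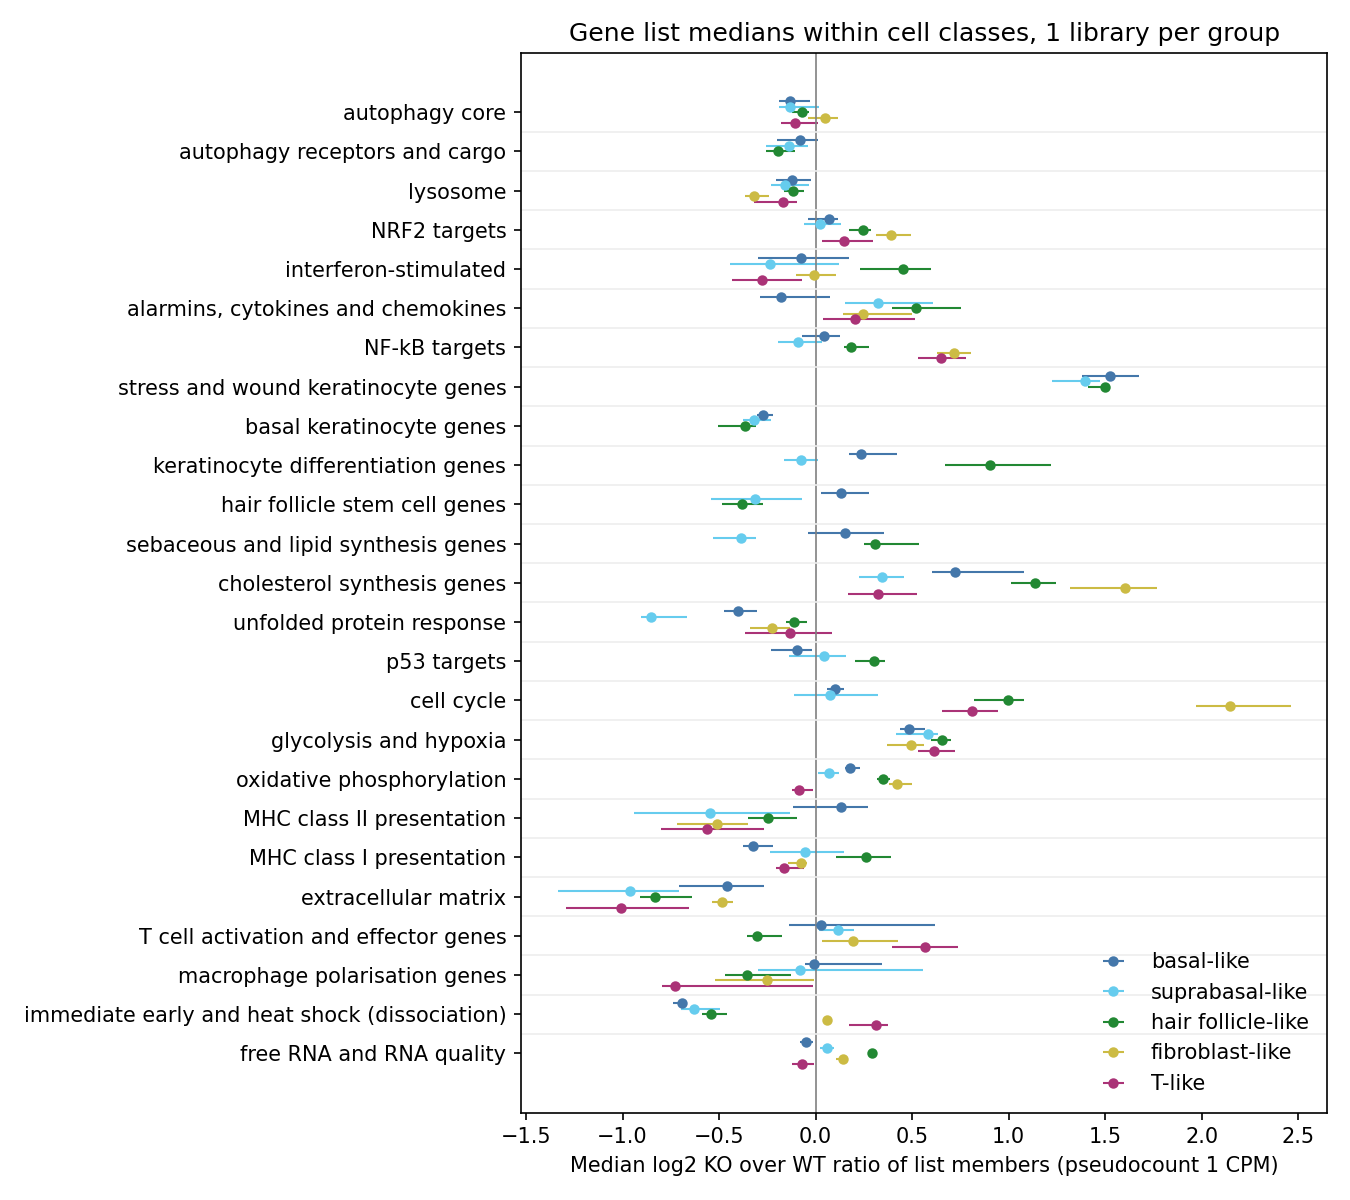
Median log2 KO over WT ratio of each gene list (pseudocount 1 CPM) in basal, suprabasal and hair follicle-like keratinocytes, fibroblast-like and T-like cells, with bars for the 95% counting interval. The stress and wound list lies at 1.52, 1.39 and 1.497 in the keratinocyte classes, and the cell cycle list at 2.14 in fibroblast-like cells.

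Sebaceous-like cells were few, 65 in WT and 174 in KO. Lcn2, which encodes the iron-withholding protein lipocalin 2, was higher by 17.01 (9.87 to 32.1) and Igf2bp2, an RNA binding protein gene, by 11.04 (4.98 to 30.5). The heat shock genes Hspa1a and Hspa1b were higher by 5.69 (4.92 to 6.62) and 5.37 (4.602 to 6.29), and Fgfbp3 by 5.65 (4.16 to 7.85). Lcn2 leads the small sebaceous cluster 35. Of the 5 lowest genes, Mup11, Cfd and Car3 had all of their WT UMIs in 1 cell. Ifi27l2a had 98.1% in 1 cell and turned to a log2 ratio of 0.93 under a stricter mitochondrial filter. Serpina3b, at 0.227 (0.171 to 0.298), had 37.8% in 1 cell.

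Fibroblast-like cells of the KO library had more cycling and sterol synthesis RNA and less collagen RNA. Of 22 cell cycle genes 21 were higher (median 2.14, 1.97 to 2.46, percentile 100), such as Cenpf at 59.6 (25.1 to 186) and Top2a, the topoisomerase of dividing cells, at 26.9 (17.3 to 44.0). By cluster the median was 2.79 in cluster 8, with 413 WT and 369 KO cells, against 0.37 (-0.040 to 0.68) in cluster 3 and 0.83 (0.56 to 1.31) in cluster 9. All 17 cholesterol synthesis genes were higher (median 1.60, 1.32 to 1.77, percentile 100), with Idi1 at 6.52 (5.04 to 8.52) and Sqle at 6.03 (4.52 to 8.15). The NF-kB list had 11 of 16 higher and 0 lower (median 0.72, 0.63 to 0.81, percentile 100), Tnfaip3, an inhibitor of that pathway, being at 2.66 (2.43 to 2.92) and Nfkbia at 2.15 (2.07 to 2.23). In clusters 3, 8 and 9 the cholesterol medians were 1.30, 1.44 and 1.01, and the NF-kB medians 0.74, 0.41 and 0.78. Extracellular matrix genes had 9 of 21 lower and 5 higher (median -0.48, -0.53 to -0.43), with Timp1, an inhibitor of matrix proteases, higher by 3.997 (3.39 to 4.72). The matrix median was -0.21 in cluster 3 and -0.58 in cluster 9, but 0.48 (0.43 to 0.53) in cluster 8. The lowest by rule were Col1a1 at 0.214 (0.212 to 0.216), Angptl1 (0.225), C1qtnf3 (0.229), Col1a2 (0.232) and Sparc (0.247), all leading genes of cluster 3, which held 882 of 1645 WT but 89 of 1109 KO fibroblast-like cells. By cluster Col1a1 was at 0.324 in cluster 3 and 0.442 in cluster 9, which held 542 of the KO cells, but at 1.64 (1.60 to 1.69) in cluster 8. The highest were Akr1c14 (9.90), which encodes a steroid dehydrogenase, Bok (6.24), Ifi205 (4.55), Itih5 (4.28) and Igfbp4 (3.90), where Akr1c14 leads cluster 8 and Ifi205 cluster 9.

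T-like cells of the KO library had more RNA of type 17 cytokines. Il17a was 76.7 CPM in WT and 359 CPM in KO, a ratio of 4.68 (4.04 to 5.44), and Il17f was higher by 7.69 (5.94 to 10.1). Il22, an epithelium-directed cytokine, had 1 WT and 468 KO UMIs, a ratio of 174 (31.0 to 6877), from 33 KO cells with 36.1% of the UMIs in 1 of them. In the T cell activation list 9 of 19 were higher and 1 lower (median 0.57, 0.39 to 0.74, percentile 100). Pdcd1, the PD-1 gene, was at 4.004 (2.31 to 7.50) and Gzmc at 0.355 (0.339 to 0.372), while Ifng was at 1.06 (0.892 to 1.27). Within cluster 15, with 89 WT and 402 KO cells, Il17a was higher by 2.72 (2.35 to 3.16), Il17f by 4.34 (3.34 to 5.74) and Il22 by 93.9 (16.8 to 3718) on 1 WT UMI. Il17a and Il17f are among the genes that define that cluster. The heat shock genes Hspa1a and Hspa1b were higher by 20.2 (13.4 to 32.0) and 10.2 (7.76 to 13.5), and Hspa1a was higher in each of clusters 6, 13 and 15. The immediate early and heat shock list had 2 of 19 higher and 0 lower in T-like cells, with a median of 0.31 (0.17 to 0.38) at percentile 99.97. Within clusters 6, 13 and 15, which the libraries fill differently, it was 0.071, 0.13 and 0.094 (-0.026 to 0.24). The chemokine gene Ccl1 was higher by 34.0 (18.4 to 71.2), but 79.3% of its KO UMIs came from 1 cell and its log2 ratio turned to -0.73 with each library clustered on its own. The lowest by rule were Rcn3 at 0.259 (0.216 to 0.310), Tnfaip8l3 (0.340), Gzmc, the fractalkine receptor gene Cx3cr1 (0.3595) and Cd160 (0.384). Gzmc and Cd160 lead cluster 28, which has genes of natural killer or innate lymphoid cells. The NF-kB list had 9 of 16 higher and 0 lower (median 0.65), with Bcl3 at 2.69 (1.82 to 4.11) and Ier3 at 2.09 (1.75 to 2.51), and by cluster its median was 0.27, 0.36 and 0.44 in clusters 6, 13 and 15. The cell cycle list had 15 of 22 higher (median 0.81), with Ccna2 at 4.11 (2.46 to 7.34) and Stmn1 at 2.70 (2.42 to 3.01), but by cluster the median was 0.094 (-0.052 to 0.35) in cluster 6, 0.41 in cluster 13 and 0.65 in cluster 15.

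Macrophage or dendritic-like cells, all of cluster 19 with 157 WT and 199 KO cells, had more cycling and glycolysis RNA in KO, with 16 of 21 (median 1.53, 1.15 to 1.82) and 9 of 15 genes higher. Of the cycling genes Ccnb2 was at 29.99 (5.08 to 1215) on 1 WT UMI and Ube2c at 12.5 (5.12 to 39.4). In the polarisation list 5 of 16 were higher and 4 lower (median 0.33, 0.076 to 0.54). Trem2, a lipid receptor gene, was higher by 7.80 (3.60 to 20.1) and the cytokine gene Il1b by 2.31 (2.17 to 2.47), Spp1 by 2.25 (1.17 to 4.599), and Folr2 was at 0.544 (0.412 to 0.716). By rule the highest were Mucl1 and Fcer2a, at 493 (136 to 4072) and 76.9 (21.01 to 639) on 2 WT UMIs each, the placental growth factor gene Pgf (15.6), Cd207, the langerin gene (7.97), and the chemokine gene Ccl4 (6.43). These rest on few KO cells: Cd207 was found in 11, Mucl1 in 12, Fcer2a in 14, Pgf in 31 and Ccl4 in 33 of 199. Of the KO UMIs 1 cell held 69.3% for Mucl1, 33.4% for Ccl4 and 24.6% for Cd207. The rule for named genes did not set Cd207 beside Langerhans-like cells, whose cluster 36 it leads. The lowest were the mast cell genes Tpsb2 (0.0246), Mrgprb1 (0.0311), Hdc (0.0526), Cpa3 (0.0765) and Cma1 (0.0907), found in 13 to 15 WT cells, and all 5 had under 20 UMIs in this class at resolution 2.0 or with a stricter mitochondrial filter. Hdc turned to a log2 ratio of 3.93 with each library clustered on its own.

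Endothelial-like cells were 182 in WT and 96 in KO, most in vascular cluster 21. Il6, the interleukin 6 gene, was higher by 3.72 (3.19 to 4.34), the granulocyte growth factor gene Csf3 by 4.73 (3.47 to 6.53) and the protease gene Adamts4 by 4.98 (3.63 to 6.91). The NF-kB list had 7 of 16 higher and 0 lower (median 0.43, 0.35 to 0.67, percentile 99.95), Tnfaip2 being at 3.72 (2.44 to 5.75) and Nfkbie at 3.15 (1.42 to 7.22). Csf3 was found in 13 KO cells, 1 of which held 29.2% of its UMIs. Hspa1a was higher by 4.08 (3.20 to 5.23), with 50.8% of its KO UMIs in 1 cell, and Stfa3 had 0 WT UMIs and 98.0% of its 101 KO UMIs in 1 cell. The lowest were Hjurp (0.321), Reln, a lymphatic marker (0.333), Nuak1 (0.401), the lipid transfer gene Pltp (0.437) and the matrix Gla protein gene Mgp (0.451).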

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

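The tests of depth, of handling stress, of shares that sum to 100 and of the barcode filter were chosen only after the results they bear on were seen. The patterns were found and weighed in the same 2 libraries, and a difference between the animals, such as age or housing, stays open for each of them and was not tested.

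Cholesterol synthesis genes had a median log2 ratio of 1.60 in fibroblast-like cells and -0.78 in sebaceous-like cells, opposite directions under the same comparison that lie 2.38 apart. The difference itself was not tested. The unnamed cluster 11 held 668 KO cells against 13 WT cells, and the unnamed cluster 27 held 156 KO cells against 0 WT cells, signals outside the classes that were compared.

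Hair matrix or shaft-like cells were 13.4% of KO and 0.0660% of WT keratinocyte-like cells. A depth gap is argued against, because with cells thinned to 1000 UMIs, and shallower cells left out, the difference was still 12.7 points. A candidate explanation is that hair follicles were in a growing phase in the KO library and in a resting phase in the WT library, as the pigment synthesis list, of genes active during hair growth, had a median log2 ratio of 1.44 in melanocyte-like cells. The unnamed clusters 0 and 7 of WT and 11 and 27 of KO may be dermal papilla cells, the signalling cells of the follicle base, in different states, as the smaller median of a dermal papilla list against fibroblast-like cells was 2.07. Whether the genotype or the timing of the hair cycle in these animals set the phase cannot be decided with 1 library each.

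Stress and wound genes were higher in KO basal and suprabasal-like cells, with medians of 1.52 and 1.39. Handling stress that raises the immediate early and heat shock list as a whole is argued against in these cells, where the list had medians of -0.69 and -0.63. The list had 0.25 in sebaceous-like and 0.31 in T-like cells (0.071 to 0.13 within T-like clusters 6, 13 and 15), where such stress stays open. Hspa1a of this list was higher in all keratinocyte-like cells pooled, so a handling difference that the list's median misses stays open too. Free RNA is argued against as the whole cause in basal-like cells, where in the KO library the list's members were at a median of 15.5 times their CPM in T-like cells, but it stays open for other classes, since the 3 or 4 members measured there had medians of 1.86 in fibroblast-like cluster 9 and 1.81 in endothelial-like cluster 21. A response of keratinocytes to interleukin 17 and interleukin 22 is consistent with a list of such response genes, whose smaller median over both classes was 0.81. However, only 6 and 4 of its 11 members were measured, and the test does not separate that response from other inflammatory signals.

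T-like cells were 5.02% of WT and 21.4% of KO cells. T-like cells per cell of every one of the 6 other classes set beside them were higher in KO, the smallest ratio being 2.12, against melanocyte-like cells. A loss of only some of these 6 classes is argued against as the whole cause. Whether T-like cells were more, or all 6 other classes fewer, cannot be decided, since both raise these ratios. Myeloid-like and sebaceous-like cells were not set beside them singly. Their shares of all cells were 2.13 and 4.03 times those in WT, against 4.25 times for T-like cells. T-like cells per sebaceous-like cell were thus nearly alike in both libraries. Hair matrix or shaft-like cells, 3 in WT and 413 in KO, rose by more than T-like cells. The result therefore holds only for the 6 classes chosen. The barcode filter is argued against as the whole cause, since without it the difference was 12.4 points. How completely each tissue was dissociated, and the live-cell sort, stay open and were not tested.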

How the results depend on the processing

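The alternatives that take suprabasal-like or hair follicle-like cells alone, or leave out hair matrix or shaft-like cells or unnamed clusters, were chosen only after the data had been seen. No paired analysis was possible because there was 1 library per group and no test. The gene ratios were those of Atg16l1 and of the named genes, which were picked for large ratios in these same libraries. Most were thus unlikely to reverse, and their count says little about other genes. Of 1083 alternative values for 101 gene ratios, 1073 kept their direction and 693 lay within the counting interval, while 10 reversed. Of 449 for 25 list medians in keratinocyte-like cells, 420 kept their direction and 262 lay within the interval, 20 reversed, and the others that changed sign were of the p53 list, whose interval included 0. Of 119 for 14 share differences, 111 kept their direction and 87 lay within the interval, and those that changed sign were of the keratinocyte-like and fibroblast-like shares, whose intervals included 0. For T-like cells the share difference ran from 12.4 to 17.6 points over these alternatives. Among the classes with gene ratios, depth limits endothelial-like and macrophage or dendritic-like cells most, and an alternative gave no value where a gene then had under 20 UMIs, as for the mast cell genes. For the values that moved beyond the counting interval or reversed, the cause was not tested, except that each scaling shifts all genes of a class by 1 factor and that weighting or leaving out sub-classes changes their mix.

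Without the filter on barcodes, share differences in points were 2.47 for keratinocyte-like cells, -1.11 for fibroblast-like cells, 12.4 for T-like cells, -14.3 for unnamed cells, 9.60 for hair matrix or shaft-like cells and -20.8 for hair follicle-like cells. The list medians were -0.40 for basal genes, -0.63 for hair follicle stem cell genes and 0.029 for free RNA. At a mitochondrial limit of 5%, share differences in points were 2.45 for keratinocyte-like cells and -20.6 for unnamed cells. The log2 ratio was 0.93 for Ifi27l2a in sebaceous-like cells. List medians there were -0.60 for immediate early genes and -0.045 for free RNA. With doublets kept, share differences in points were -0.905 for fibroblast-like cells, -17.2 for unnamed cells and 5.63 for basal-like cells. The list medians were 0.34 for differentiation, 0.68 for sebaceous genes, 0.91 for cholesterol synthesis and 1.44 for cell cycle. At resolution 2.0, share differences in points were 14.1 for T-like cells, -16.6 for unnamed cells, 10.4 for hair matrix or shaft-like cells, -20.1 for hair follicle-like cells and 1.60 for sebaceous-like cells. List medians there were -0.013 for NF-kB targets, 0.29 for differentiation, -0.76 for hair follicle stem cell genes, -0.097 for p53 targets, 1.86 for cell cycle and -0.74 for MHC class II. Extracellular matrix had -0.63 and immediate early genes -0.70. When each library was clustered on its own, share differences in points were 3.16 for fibroblast-like cells, 13.3 for T-like cells, -0.382 for mural-like cells, 0.0399 for basal-like cells, 8.50 for hair matrix or shaft-like cells and -13.7 for hair follicle-like cells. The log2 ratios were 0.46 for Cxcl14 in basal-like cells, 3.93 for Hdc in macrophage or dendritic-like cells and -0.73 for Ccl1 in T-like cells. The list medians were 0.28 for differentiation and 1.31 for cell cycle. In cells thinned to 1000 UMIs before summing, list medians were -0.22 for autophagy receptors, 0.27 for alarmins, 0.22 for NF-kB targets, 1.22 for stress and wound genes, -0.42 for basal genes and 1.04 for sebaceous genes. Cholesterol synthesis had 1.10, unfolded protein response -0.063, p53 targets 0.17, cell cycle 1.59, glycolysis 0.65 and oxidative phosphorylation 0.44. MHC class II had -0.44, extracellular matrix -1.18, T cell activation -0.20, immediate early genes -0.59 and free RNA -0.041.

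Under TMM scaling, list medians were -0.021 for autophagy core, -0.079 for autophagy receptors, -0.15 for lysosomal genes, -0.39 for basal genes, 0.32 for differentiation and -0.60 for hair follicle stem cell genes. Sebaceous genes had 0.66, cholesterol synthesis 0.91, cell cycle 1.44, glycolysis 0.66, oxidative phosphorylation 0.44 and MHC class I -0.030. Immediate early genes had -0.57 and free RNA -0.015. Scaled by the median of ratios, list medians were -0.013 for autophagy core, -0.071 for autophagy receptors, -0.14 for lysosomal genes, 0.11 for NF-kB targets, -0.39 for basal genes and 0.33 for differentiation. Hair follicle stem cell genes had -0.59, sebaceous genes 0.67, cholesterol synthesis 0.92, cell cycle 1.45, glycolysis 0.67 and oxidative phosphorylation 0.45. MHC class I had -0.022, immediate early genes -0.56 and free RNA -0.0076. As means over cells, list medians were 0.90 for stress and wound genes, -0.42 for basal genes, 0.46 for differentiation, 0.80 for sebaceous genes, 1.22 for cholesterol synthesis and 0.092 for p53 targets. Cell cycle had 1.53, glycolysis 0.57, MHC class I -0.021 and free RNA -0.024. Counting members from 1 UMI up, list medians were 0.63 for stress and wound genes, 0.13 for differentiation and -0.25 for macrophage polarisation. Counting only members with at least 200 UMIs, list medians were -0.031 for interferon-stimulated genes, 0.0088 for alarmins, 0.98 for stress and wound genes, 0.035 for differentiation, 0.54 for glycolysis and -0.27 for T cell activation. With a pseudocount of 10 CPM, list medians were 0.15 for NRF2 targets, 0.044 for interferon-stimulated genes, 0.45 for stress and wound genes, 0.12 for differentiation, -0.61 for hair follicle stem cell genes and 0.35 for sebaceous genes. Cholesterol synthesis had 0.76, cell cycle 1.19, glycolysis 0.46, MHC class II -0.34, extracellular matrix -0.25 and T cell activation 0.059. Macrophage polarisation had -0.047.

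Weighting the sub-classes equally, the log2 ratios were -0.35 for Atg16l1 and -0.075 for Fabp5. The list medians were -0.14 for lysosomal genes, 0.013 for NRF2 targets, -0.0028 for NF-kB targets, 1.06 for stress and wound genes, -0.25 for basal genes and -0.19 for hair follicle stem cell genes. Sebaceous genes had -0.28, cholesterol synthesis 0.013, unfolded protein response -0.40, cell cycle 0.20, glycolysis 0.53 and oxidative phosphorylation 0.049. MHC class II had -0.26, MHC class I -0.0092, immediate early genes -0.50 and free RNA -0.042. In basal-like cells alone, the log2 ratios were 0.14 for Pdzrn4 and 0.82 for Kcnk2. List medians there were -0.13 for autophagy core, -0.083 for autophagy receptors, -0.12 for lysosomal genes, 0.069 for NRF2 targets, -0.077 for interferon-stimulated genes and -0.18 for alarmins. Stress and wound genes had 1.52, basal genes -0.27, hair follicle stem cell genes 0.13, sebaceous genes 0.15, cholesterol synthesis 0.72 and unfolded protein response -0.40. The p53 targets had -0.097, cell cycle 0.10, glycolysis 0.48, oxidative phosphorylation 0.18, MHC class II 0.13 and MHC class I -0.33. Extracellular matrix had -0.46, T cell activation 0.029, macrophage polarisation -0.0074, immediate early genes -0.69 and free RNA -0.051. For suprabasal-like cells alone, the log2 ratios were -0.79 for Atg16l1, -0.67 for Klk7, -1.22 for Tk1 and 1.10 for Kcnk2. The list medians were -0.13 for autophagy core, -0.16 for lysosomal genes, 0.023 for NRF2 targets, -0.24 for interferon-stimulated genes, 0.33 for alarmins and -0.091 for NF-kB targets. Stress and wound genes had 1.39, basal genes -0.32, differentiation -0.076, hair follicle stem cell genes -0.32, sebaceous genes -0.39 and cholesterol synthesis 0.34. Unfolded protein response had -0.85, cell cycle 0.075, oxidative phosphorylation 0.067, T cell activation 0.11, macrophage polarisation -0.083 and free RNA 0.060. From hair follicle-like cells alone, list medians were -0.12 for lysosomal genes, 0.45 for interferon-stimulated genes, 0.52 for alarmins, 0.19 for NF-kB targets, 1.497 for stress and wound genes and -0.37 for basal genes. Differentiation had 0.90, hair follicle stem cell genes -0.38, sebaceous genes 0.31, cholesterol synthesis 1.14, p53 targets 0.30 and cell cycle 0.99. Glycolysis had 0.65, oxidative phosphorylation 0.35, MHC class II -0.24, MHC class I 0.26, T cell activation -0.30 and immediate early genes -0.54. Free RNA had 0.29. Leaving out hair matrix or shaft-like cells, share differences in points were -2.58 for keratinocyte-like cells, 17.6 for T-like cells, 10.9 for basal-like cells, 2.57 for suprabasal-like cells and -18.6 for hair follicle-like cells. The list medians were 0.28 for alarmins, 0.15 for NF-kB targets, 1.01 for stress and wound genes, -0.30 for basal genes, 0.36 for differentiation and 0.84 for sebaceous genes. Unfolded protein response had -0.24, p53 targets 0.11, cell cycle 0.79, glycolysis 0.65, oxidative phosphorylation 0.35 and MHC class II -0.41. Immediate early genes had -0.61 and free RNA 0.14. After the unnamed clusters were left out of the total, share differences in points were -11.7 for keratinocyte-like cells, -4.36 for fibroblast-like cells, -0.886 for endothelial-like cells, -1.70 for mural-like cells and -1.49 for Schwann-like cells.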

Other observations

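The gene lists and cluster values in this part were chosen only after the first results had been seen. Melanocyte-like cells, 224 in WT and 298 in KO, had more RNA of pigment synthesis genes in the KO library. Of 9 genes 8 were at least 1.5 times higher and 0 lower, with a median log2 ratio of 1.44 (1.31 to 1.56) at percentile 100 of matched random lists. Tyr, the tyrosinase gene and first enzyme of melanin synthesis, was higher by 2.93 (2.53 to 3.41), Mlana by 2.72 (2.51 to 2.96), Slc24a5, a melanosomal ion exchanger gene, by 2.97 (2.498 to 3.54) and Gpr143 by 4.97 (2.84 to 9.36). Oca2 had 0 WT and 133 KO UMIs. Dct, an enzyme gene of the same path, was closer to WT at 1.25 (1.22 to 1.28).

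The unnamed clusters differed from fibroblast-like cells of their own library in genes of the dermal papilla. In WT clusters 0 and 7 together, led by Pappa2, Slc26a7, Dkk2 and Igfbp3, 12 of 13 such genes were higher than in WT fibroblast-like cells. Among them, Lef1, a transcription factor of Wnt signalling, was higher by 15.4 (13.6 to 17.6) and the growth factor gene Fgf10 by 8.55 (7.38 to 9.95). In KO clusters 11 and 27, 13 of 13 were higher than in KO fibroblast-like cells, with a median of 3.60 (3.28 to 3.96), Lef1 by 30.9 (25.0 to 38.6) and Bmp6 by 72.6 (34.8 to 182). The dermal papilla is one candidate source of these cells, from the smaller median of 2.07, and no other type was tested.

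The response list for interleukin 17 and 22 had 6 of 6 measured genes higher in basal-like cells, with Lcn2 at 16.9 (4.41 to 144) on 2 WT UMIs and Steap4 at 3.34 (2.63 to 4.28). It had 2 of 4 higher in suprabasal-like cells (median 0.90) and 5 of 5 in hair follicle-like cells (median 1.10), with 0 lower in each. Areg, which encodes the growth factor amphiregulin, was higher in KO T-like cells by 1.89 (1.76 to 2.02) in cluster 6, 1.58 (1.43 to 1.76) in cluster 13 and 1.79 (1.52 to 2.12) in cluster 15, but was at 1.13 (0.839 to 1.53) in cluster 28. Mast cell genes in macrophage or dendritic-like cells had 6 of 6 lower (median -3.32, -3.62 to -3.18). This list holds Tpsb2, Cpa3 and Cma1, already named among the lowest genes there, so its median restates values that rest on 13 to 15 WT cells. Those genes had under 20 UMIs in this class at resolution 2.0.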
